A study of Homo sapiens with 6 samples.

How the data were processed

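RNA from T98G cells was measured in 6 libraries, 2 each of untreated cells (NT), cells transfected with a short hairpin vector against SRPK1 in pLKO.1 (shSRPK1) and cells transfected with an SRPK1 expression vector in pcDNA3.1 (oeSRPK1), per the labels. Per the labels' protocols, transfection was transient with a lipid reagent, RNA had an integrity number above 8, and poly(A) libraries were sequenced as paired reads of 101 bp. The series text calls the libraries of a group biological replicates without saying whether they came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

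The authors' deposited values were whole-number read counts per gene, not normalised, 1 table per library. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic and aligned to hg38 with STAR 2.5.3. The counting tool, the annotation release and the strand setting were not given in the sources used here. Each table ended in 5 entries that name no gene, laid out as htseq-count does, and these were kept out of library sizes and tests. Reads in no annotated gene made up 8.22%, 9.31%, 9.81%, 11.1%, 8.60% and 8.13% of the total in NT 1, NT 2, shSRPK1 1, shSRPK1 2, oeSRPK1 1 and oeSRPK1 2, reads aligned to several places 11.95%, 12.3%, 13.1%, 12.5%, 12.9% and 12.8%, and ambiguous reads 3.37%, 3.28%, 3.04%, 3.07%, 3.21% and 3.30%. Without a stated strand, reads of overlapping and antisense genes cannot be separated, and reads shared by near-identical copies were lost or split.

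The tables held 60483 gene ids. Symbols came from a table of gene names for 41124 ids and from GENCODE 29 (GRCh38) alone for 15629, and 3730 had none. The 10 genes with most reads took 9.00%, 8.88%, 9.90%, 9.99%, 7.12% and 6.75% of the gene reads in the order above. Gene positions are those of GENCODE 29. The depth of a library sets its precision: a floor of 3 counts stood for 0.291, 0.212, 0.227, 0.287, 0.135 and 0.776 CPM. The intervals of the summed muscle markers and the floors cover counting error only, since the reads carried no molecular identifiers. The intervals of fold changes come from the edgeR fit described below and include the spread between libraries.

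Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its group setting, a minimum count of 10 and a minimum total of 15, which left 14732 genes with 99.8% of the gene reads. Counts were scaled by TMM, and glmQLFit with robust estimation and glmQLFTest were fitted to all 6 libraries, which share 1 estimate of the spread (biological coefficient of variation 14.5%). A Benjamini-Hochberg adjusted p under 0.05 made a call. The comparisons were shSRPK1 against NT, oeSRPK1 against NT and oeSRPK1 against shSRPK1. Because the replicates of shSRPK1 differed more than the others, the shared spread is too small for shSRPK1 and too large for NT and oeSRPK1. Normalised CPM uses the TMM library sizes, and log2 CPM a prior count of 2.

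Before the data were examined, 41 gene lists, the design, the alternatives and the rule for named genes were fixed. 40 lists had at least 3 tested genes, and were tested by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 120 list tests. With an estimated correlation, 0 of the 53 list calls held. The rotation test fry, which asks whether the genes of a list move on balance in one direction and does not compare the list with other genes, kept 20 of the 53. Named genes were SRPK1, SRPK2 and CLK1, then in each comparison the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, up to 4 genes with the smallest adjusted p from each list with a call or with 3 called genes, and 8 genes called in opposite directions. Some were left out for length, a few others chosen by the rule are not reported here, and exceptions are named where they stand.

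Alternatives were DESeq2 size factors, upper-quartile scaling, library sizes without SRPK1, no filter and a stricter filter (CPM of 5 in 2 libraries), an adjusted p under 0.01, an added minimum of 2-fold, DESeq2 1.42.0, limma-voom, a fit of only the libraries compared, a fit with the replicate number as a block, and leaving out each library in turn, where a lone library was assumed to vary like the other groups. Chosen after seeing the data were thinning of all libraries to the shallowest, offsets on GC content and length (known for 99.4% of tested genes), leaving out muscle transcripts, and limma-voom with a spread per group. The steps were tested on simulated data, drawn from the means and library sizes of the data with 200 changed genes. For shSRPK1 against NT edgeR found 19.4% of genes changed 1.5-fold, 69.7% at 2-fold and 96.9% at 4-fold (14479 genes), for oeSRPK1 against NT 16.9%, 66.7% and 90.5% (14449 genes), and for oeSRPK1 against shSRPK1 12.1%, 62.7% and 87.9% (14466 genes). False calls were 6.20%, 5.88% and 6.09% of the calls. The simulated data had the same spread in all groups, unlike the data. These rates therefore do not measure recovery or false calls under the larger spread of shSRPK1. Comparisons that share NT were set beside 20 simulations of unchanged groups. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.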

Results

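Poly(A) RNA was sequenced from T98G cells, an established human glioblastoma cell line, in 6 libraries. Untreated cells (NT) gave 2 libraries, cells transiently transfected with a short hairpin vector against SRPK1 (shSRPK1) gave 2, and cells transiently transfected with an SRPK1 expression vector (oeSRPK1) gave 2. SRPK1 is a cytoplasmic and nuclear kinase that phosphorylates serine/arginine-rich splicing factors, and the design asked how the transcripts of these cells changed with less and with more of it. Reads counted in genes were 9891606 in NT 1, 13634038 in NT 2, 13650909 in shSRPK1 1, 10792385 in shSRPK1 2, 22691215 in oeSRPK1 1 and 3891549 in oeSRPK1 2. A level of 3 counts, taken as the floor, stood for 0.135 CPM in oeSRPK1 1 and for 0.776 CPM in oeSRPK1 2. No transfected control library was used here, so transfection and the construct changed together in both comparisons with NT, while oeSRPK1 against shSRPK1 set transfected cells against transfected cells. Those groups received different vectors, so that comparison does not separate SRPK1 from other differences between the constructs.

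The oeSRPK1 libraries lay apart from the other 4 on the first principal component, which held 52.5% of the variance, and the shSRPK1 libraries lay apart from NT on the second, which held 24.4%. The replicates of shSRPK1 differed more than those of the other groups. Their chi-square per gene was 45.2 over 14143 genes, against 4.44 for NT and 8.04 for oeSRPK1, and their log2 CPM correlated at 0.975, against 0.992 and 0.984. All fold changes are given as log2 fold change ± standard error (SE) from edgeR's quasi-likelihood test over all 6 libraries (n = 2 per group), with Benjamini-Hochberg adjusted p. Of 441 calls made on the named genes, 200 were kept without NT 1, 208 without NT 2, 429 without shSRPK1 1, 430 without shSRPK1 2, 115 without oeSRPK1 1 and 243 without oeSRPK1 2, and 0 turned direction.

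SRPK1 itself differed little between the groups. It (ENSG00000096063.13, GRCh38 chromosome 6, 35832966 to 35921342, minus strand) had 152.5 and 140.4 normalised CPM in NT, 113.1 and 140.1 in shSRPK1, and 190.3 and 168.0 in oeSRPK1, from 1571, 1988, 1498, 1465, 4231 and 650 reads. The group means were 146 ± 8.58 CPM in NT, 127 ± 19.1 in shSRPK1 and 179 ± 15.8 in oeSRPK1 (SD, n = 2). In shSRPK1 the level was 0.864 times that of NT (95% interval 0.691 to 1.08, log2 fold change -0.21 ± 0.14, edgeR adjusted p = 0.360), and shSRPK1 2 was level with NT 2. In oeSRPK1 it was 1.23 times that of NT (95% interval 0.980 to 1.53, 0.29 ± 0.14, edgeR adjusted p = 0.175). Between oeSRPK1 and shSRPK1 it was 1.42 times higher (95% interval 1.13 to 1.78, 0.50 ± 0.14, edgeR adjusted p = 0.0377). That call was lost in edgeR without NT 1 (adjusted p = 0.0945), NT 2 (0.0939), oeSRPK1 1 (0.308) or oeSRPK1 2 (0.0997), when only the libraries of both groups were fitted (0.0920), with a replicate block (0.0609), and with offsets on GC content and length (0.0529). The difference between shSRPK1 and NT passed in edgeR without shSRPK1 2 (-0.37, adjusted p = 0.0208), and that between oeSRPK1 and NT passed without shSRPK1 1 (0.0267) or shSRPK1 2 (0.0319), when only those groups were fitted (0.0232), and in limma-voom with a spread per group (adjusted p = 0.0286).

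CLK1, a nuclear kinase of the same splicing factors (ENSG00000013441.14, chromosome 2, 200853009 to 200864744, minus strand), rose in both transfected groups. It reached 2.44 times the NT level in shSRPK1 (95% interval 1.97 to 3.03, 1.29 ± 0.14, edgeR adjusted p = 0.00396) and 1.47 times in oeSRPK1 (95% interval 1.18 to 1.82, 0.55 ± 0.14, edgeR adjusted p = 0.0256). It was lower in oeSRPK1 than in shSRPK1 (-0.73 ± 0.13, edgeR adjusted p = 0.00953). SRPK2, the close relative of SRPK1 (ENSG00000135250.15, chromosome 7, 105110704 to 105399308, minus strand), did not pass in any of the 3 comparisons, at 0.18 ± 0.14, 0.01 ± 0.14 and -0.17 ± 0.14 (edgeR adjusted p = 0.427, 0.959 and 0.417). In edgeR without NT 1, CLK1 no longer passed in shSRPK1 (adjusted p = 0.0943). Its call in oeSRPK1 against NT was lost in edgeR without NT 1 (adjusted p = 0.241), NT 2 (0.0910), oeSRPK1 1 (0.187) or oeSRPK1 2 (0.134), and that against shSRPK1 without oeSRPK1 1 (0.124) or oeSRPK1 2 (0.0697). Without shSRPK1 1, SRPK2 passed in edgeR in shSRPK1 against NT (0.36, adjusted p = 0.0189) and in oeSRPK1 against shSRPK1 (-0.38, adjusted p = 0.0115).

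**Figure D1:**
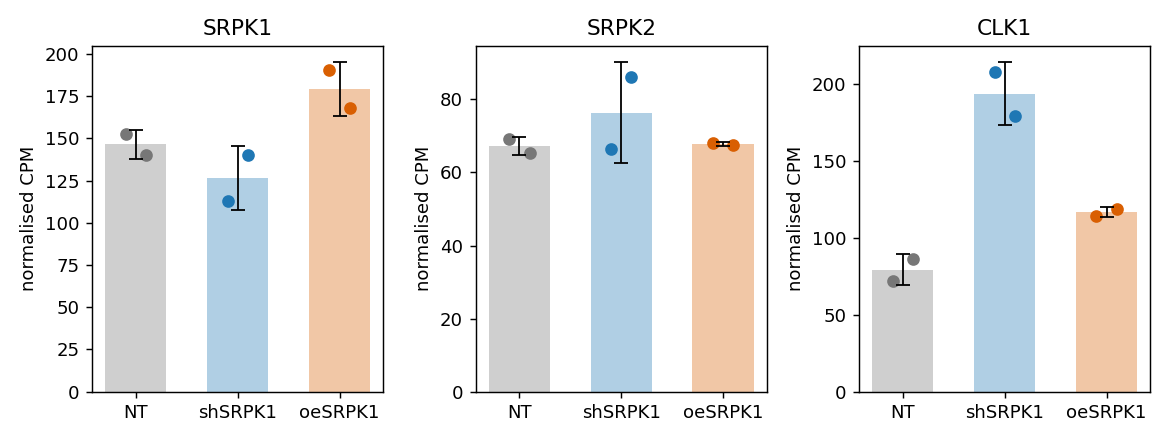
Normalised CPM of SRPK1, SRPK2 and CLK1 in NT, shSRPK1 and oeSRPK1; points are the 2 libraries of a group, bars their mean and error bars the SD. SRPK1 means run from 127 CPM in shSRPK1 to 179 CPM in oeSRPK1, and CLK1 stands highest in shSRPK1.

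In shSRPK1 against NT, most of the interferon-stimulated genes tested were called higher. IFI44L (4.75 ± 0.63), IFIT1, an antiviral protein that binds foreign RNA (4.32 ± 0.62), CMPK2 (4.20 ± 0.64) and MX1, an antiviral GTPase (4.13 ± 0.36), had edgeR adjusted p = 0.0204, 0.0245, 0.0249 and 0.00433. IFI44L had 123 reads in NT 1 and 524 in NT 2, and IFIT1 101 and 334, so their NT levels differed between libraries. OAS1 (3.96 ± 0.29), IFI6 (3.91 ± 0.50) and IFITM1 (3.90 ± 0.34) followed, with edgeR adjusted p = 0.00183, 0.0147 and 0.00396. Of the 68 tested interferon-stimulated genes, 54 rose and 0 fell (61 and 0 adjusted over the list alone), with a median of 2.17. The list passed camera (adjusted p = 4.79e-91), but not with an estimated correlation (adjusted p = 0.389 with an estimated correlation). PARP9 (2.27 ± 0.16), IFI44 (3.62 ± 0.25), OAS3 (3.26 ± 0.24) and BST2, which tethers virus particles to the cell surface (1.82 ± 0.14), had the smallest adjusted p of the list, each at 0.00124 in edgeR. CCDC194 also rose, on few reads (1 and 4 in NT, 38 and 109 in shSRPK1, edgeR adjusted p = 0.0203). Without NT 1 and without NT 2, 15 and 18 interferon-stimulated genes were called higher, and 30 when only the libraries of both groups were fitted.

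Some genes of the lists of cytosolic ribosomal proteins and G1/S genes were called lower in shSRPK1, as were single genes with large falls. RIMS3, a presynaptic protein (-2.35 ± 0.17), and REEP1 (-2.21 ± 0.34) had edgeR adjusted p = 0.00124 and 0.0121. CLGN (-2.18 ± 0.45), RNF157 (-1.96 ± 0.35) and the epithelial keratin KRT7 (-1.96 ± 0.20) had edgeR adjusted p = 0.046, 0.0197 and 0.00369. PAPPA2, a protease of insulin-like growth factor binding proteins, had 24 and 32 reads in NT and 2 and 1 in shSRPK1 (edgeR adjusted p = 0.005). Of 79 cytosolic ribosomal proteins, 24 fell and 0 rose (46 and 0 adjusted over the list alone, median -0.37), among them RPLP0 (-0.98 ± 0.13), RPL9 (-0.81 ± 0.13) and RPS12 (-0.74 ± 0.12). Camera gave that list adjusted p = 3.64e-13, and adjusted p = 0.650 with an estimated correlation. Of 60 G1/S genes, 9 fell and 0 rose (24 and 0 adjusted over the list alone), among them UNG (-1.0 ± 0.14), WDR76 (-1.24 ± 0.23) and the replication clamp PCNA (-0.90 ± 0.18). The list had camera adjusted p = 8.94e-13, and adjusted p = 0.650 with an estimated correlation. The G1/S median was -0.30 in shSRPK1 1 and -0.89 in shSRPK1 2, relative to the NT mean. With NT 1, NT 2, shSRPK1 1, shSRPK1 2, oeSRPK1 1 and oeSRPK1 2 left out in turn, 0, 0, 57, 45, 1 and 1 cytosolic ribosomal proteins and 0, 0, 50, 22, 1 and 2 G1/S genes were called lower.

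Some genes on the lists of extracellular matrix, hypoxia and glycolysis, and cholesterol biosynthesis were called higher in shSRPK1. Of 46 genes of the extracellular matrix list, 15 rose and 1 fell (29 and 1 adjusted over the list alone), with the collagens COL8A1 (1.61 ± 0.15), COL5A1 (1.51 ± 0.15), COL5A2 (0.93 ± 0.12) and COL4A1 (0.79 ± 0.11) at edgeR adjusted p = 0.00264, 0.0034, 0.00841 and 0.0094. Of 48 genes of the hypoxia and glycolysis list, 12 rose and 1 fell (24 and 2 adjusted over the list alone), with the glucose transporter SLC2A3 (1.84 ± 0.26), ADM (2.04 ± 0.28), P4HA1 (0.97 ± 0.18) and KDM3A (1.13 ± 0.21) at edgeR adjusted p = 0.0118, 0.0118, 0.0203 and 0.0211. Of 37 genes of the cholesterol biosynthesis and SREBP targets list, 11 rose and 0 fell (18 and 3 adjusted over the list alone). They included STARD4, a sterol carrier (2.29 ± 0.27), the sterol regulators SREBF2 (0.93 ± 0.14) and SREBF1 (0.83 ± 0.13), and the desaturase SCD (1.64 ± 0.24). Camera gave these 3 lists adjusted p = 1.01e-08, 5.44e-10 and 2.69e-06, and adjusted p = 0.389, 0.633 and 0.747 with an estimated correlation. Relative to NT, the list medians were 0.56 and 0.45 (extracellular matrix), 1.09 and 0.35 (hypoxia and glycolysis) and 0.82 and 0.20 (cholesterol) in shSRPK1 1 and shSRPK1 2. With the libraries left out in the order above, 0, 1, 25, 26, 7 and 7 extracellular matrix genes, 0, 0, 26, 38, 2 and 2 genes of hypoxia and glycolysis, and 0, 1, 13, 23, 1 and 2 of cholesterol biosynthesis and SREBP targets were called higher.

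Of 37 genes in the SR proteins list, which holds the splicing factors that SRPK1 can phosphorylate and their relatives, 6 rose and 1 fell in shSRPK1 (9 and 1 adjusted over the list alone). LUC7L (0.78 ± 0.13), LUC7L3 (0.76 ± 0.13), SCAF4 (0.74 ± 0.13) and SRSF1 (0.62 ± 0.12) had edgeR adjusted p = 0.0162, 0.0169, 0.0196 and 0.0217. The camera test gave adjusted p = 0.0193, and adjusted p = 0.618 with an estimated correlation. With the libraries left out in the order above, 0, 0, 13, 18, 0 and 0 genes of the SR proteins list were called higher, and without NT 1 the list did not pass camera (adjusted p = 0.0722). Of 62 core spliceosome genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.558), with 0 called without NT 1, NT 2, oeSRPK1 1 or oeSRPK1 2, 4 higher and 14 lower without shSRPK1 1, and 8 and 8 without shSRPK1 2. In all, 1352 of 14732 tested genes changed in shSRPK1 against NT, 800 higher and 552 lower, while 4237 had an unadjusted p under 0.05. The count was 29 without NT 1, 55 without NT 2, 3923 without shSRPK1 1, 4595 without shSRPK1 2, 240 without oeSRPK1 1, 263 without oeSRPK1 2, and 129 when only the libraries of both groups were fitted.

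In oeSRPK1 against NT, most genes on the interferon-stimulated and the NF-kB and inflammatory lists were called higher, and most NRF2 targets lower. ISG15, a ubiquitin-like modifier (3.95 ± 0.23), PARP9 (2.67 ± 0.16), OAS3 (3.76 ± 0.24) and SP100 (2.15 ± 0.16) had edgeR adjusted p = 0.000294, 0.000294, 0.000351 and 0.000426. RSAD2, an antiviral enzyme (5.55 ± 0.97), and IFI27 (4.73 ± 0.70) had the largest rises of the list, with edgeR adjusted p = 0.0239 and 0.0134. Their NT libraries differed, with 9 and 77 reads of RSAD2 and 35 and 257 of IFI27 in NT 1 and NT 2. The list median relative to the NT mean was -0.14 in NT 1 and 0.14 in NT 2. Of the 68 interferon-stimulated genes, 61 rose and 1, GBP2, fell (65 and 1 adjusted over the list alone, median 2.55). The list had camera adjusted p = 4.38e-82, and adjusted p = 0.389 with an estimated correlation. GBP2 was named after its value was seen. Without NT 1, NT 2, oeSRPK1 1 and oeSRPK1 2, 37, 45, 41 and 57 interferon-stimulated genes were called higher.

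Of 37 genes of the NF-kB and inflammatory genes list, 29 rose and 0 fell (32 and 0 adjusted over the list alone, median 1.30). The signalling adaptor TRAF1 (3.42 ± 0.18), the cytokine IL6 (2.53 ± 0.17), the apoptosis inhibitor BIRC3 (2.70 ± 0.18) and the growth factor CSF2 (4.97 ± 0.35) had edgeR adjusted p = 0.000282, 0.000378, 0.000378 and 0.000392. CCL5, a chemokine, rose by 4.73 ± 0.37 on 2 and 3 reads in NT (edgeR adjusted p = 0.000454). Of 28 genes of the MAPK pathway output list, 19 rose and 0 fell (21 and 0 adjusted over the list alone, median 1.11), with HBEGF, a ligand of the EGF receptor (2.42 ± 0.19), LIF (1.74 ± 0.14), MAFF (1.92 ± 0.16) and UPP1 (1.65 ± 0.13) at edgeR adjusted p = 0.000454, 0.000454, 0.000556 and 0.000426. Camera gave the NF-kB list adjusted p = 1.28e-32 and the MAPK list adjusted p = 5.26e-18, and both had adjusted p = 0.389 with an estimated correlation. ESM1, a secreted proteoglycan, had 1 and 2 reads in NT against 233 and 41 in oeSRPK1 (edgeR adjusted p = 0.00114). With NT 1, NT 2, oeSRPK1 1 and oeSRPK1 2 left out in turn, 12, 19, 11 and 20 genes of NF-kB and inflammatory genes and 11, 10, 8 and 13 of MAPK pathway output were called higher.

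Of 31 NRF2 targets, genes of the oxidant and xenobiotic defence, 25 fell and 0 rose in oeSRPK1 (26 and 0 adjusted over the list alone, median -1.34). PRDX1 (-1.35 ± 0.14), TKT (-1.28 ± 0.14) and NQO1 (-2.13 ± 0.24) had edgeR adjusted p = 0.00142, 0.00154 and 0.00166. Among the largest falls of all genes were the aldehyde dehydrogenases ALDH3A1 (-3.63 ± 0.45) and ALDH1A1 (-3.36 ± 0.64), the aldo-keto reductase AKR1C1 (-3.08 ± 0.33), the transporter SLC47A1 (-3.43 ± 0.38) and the matrix protein POSTN (-3.36 ± 0.82), with edgeR adjusted p = 0.0056, 0.015, 0.00226, 0.00165 and 0.0393. CES1P1 (-4.18 ± 0.96, edgeR adjusted p = 0.0326), a pseudogene, is uncertain because its reads could come from its parent gene. PLEKHS1 (-3.68 ± 0.72) and EFCC1 (-3.67 ± 0.47) had edgeR adjusted p = 0.0137 and 0.00264. They had 52 and 69 and 38 and 51 reads in NT against 9 and 1 and 5 and 2 in oeSRPK1. Both were under the floor of 3 counts in oeSRPK1 2, so the sizes of their falls are uncertain. Of 60 G1/S genes, 32 fell and 0 rose (36 and 0 adjusted over the list alone, median -0.85), with UNG (-1.97 ± 0.16) and CDCA7 (-2.19 ± 0.20) among them. Camera gave the NRF2 list adjusted p = 1.54e-23 and the G1/S list adjusted p = 3.62e-16, and adjusted p = 0.495 and 0.633 with an estimated correlation. With NT 1, NT 2, shSRPK1 1, shSRPK1 2, oeSRPK1 1 and oeSRPK1 2 left out in turn, 12, 12, 27, 27, 7 and 13 NRF2 targets and 5, 10, 53, 54, 2 and 14 G1/S genes were called lower.

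Of 15 mitochondrially encoded genes, 9 fell and 0 rose in oeSRPK1 (10 and 0 adjusted over the list alone), with MT-ND5 (-1.08 ± 0.17), MT-CYB (-0.76 ± 0.14) and MT-CO3 (-0.83 ± 0.16) at edgeR adjusted p = 0.00626, 0.00978 and 0.0107. The list had camera adjusted p = 7.98e-05, and adjusted p = 0.495 with an estimated correlation. Without NT 1, NT 2, oeSRPK1 1 and oeSRPK1 2, 0, 0, 0 and 2 mitochondrially encoded genes were called lower. Of 22 replication-dependent histones, 12 rose and 0 fell (15 and 0 adjusted over the list alone), with H2BC5 (1.44 ± 0.18) and H1-2 (1.12 ± 0.14) at edgeR adjusted p = 0.00234 and 0.00248. In shSRPK1, 6 of these histones rose and 0 fell (15 and 0 adjusted over the list alone), with H2AC6 (1.73 ± 0.24) and H3C10 (2.11 ± 0.38) at edgeR adjusted p = 0.0105 and 0.0196. Camera gave the histones adjusted p = 1.66e-08 in oeSRPK1 and 3.93e-08 in shSRPK1, and adjusted p = 0.495 and 0.455 with an estimated correlation. Most histone transcripts lack a poly(A) tail and come from near-identical copies, so their values are uncertain. With NT 1, NT 2, oeSRPK1 1 and oeSRPK1 2 left out in turn, 3, 5, 0 and 8 replication-dependent histones were called higher in oeSRPK1. Left out in the same order, they gave 0, 0, 1 and 1 in shSRPK1, and without shSRPK1 1, 14.

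Of 20 listed epithelial markers, 7 were tested and 13 had too few reads. Of the 7 tested, 5 rose and 0 fell in oeSRPK1 (5 and 1 adjusted over the list alone), with the keratin KRT7 (1.85 ± 0.17) and the mucin MUC1 (1.31 ± 0.25) at edgeR adjusted p = 0.000764 and 0.0111. DSP and ELF3, also called, rested on 1 and 3 and on 3 and 7 reads in NT. Both passed the count filter only through their reads in oeSRPK1 (55 and 6, 41 and 7). The number of rises and the camera result are thus partly set by the filter. Camera gave adjusted p = 0.000663, and adjusted p = 0.433 with an estimated correlation. Without NT 1, NT 2, oeSRPK1 1 and oeSRPK1 2, 1, 1, 1 and 2 epithelial markers were called higher. Transcripts of muscle were also present in oeSRPK1. The markers do not settle the type of muscle. ACTA1, the skeletal actin (ENSG00000143632.13, chromosome 1, 229431245 to 229434098, minus strand), had 1 and 2 reads in NT, 1 and 37 in shSRPK1, and 1646 and 3469 in oeSRPK1. RYR1, the muscle calcium release channel, had 0 and 1 in NT against 85 and 144 in oeSRPK1, and KLHL41 had 0 and 1 against 52 and 88. Summed over 52 muscle markers, the CPM without scaling factors was 5.36 and 5.57 in NT, 6.30 and 23.6 in shSRPK1, and 347 and 4205 in oeSRPK1 1 and oeSRPK1 2. In all, 3036 genes changed in oeSRPK1 against NT, 1644 higher and 1392 lower, while 5255 had an unadjusted p under 0.05. The count was 3114 with the muscle transcripts left out. It was 379 without NT 1, 481 without NT 2, 6349 without shSRPK1 1, 6415 without shSRPK1 2, 293 without oeSRPK1 1, 993 without oeSRPK1 2, and 6331 when only the libraries of both groups were fitted.

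**Figure D2:**
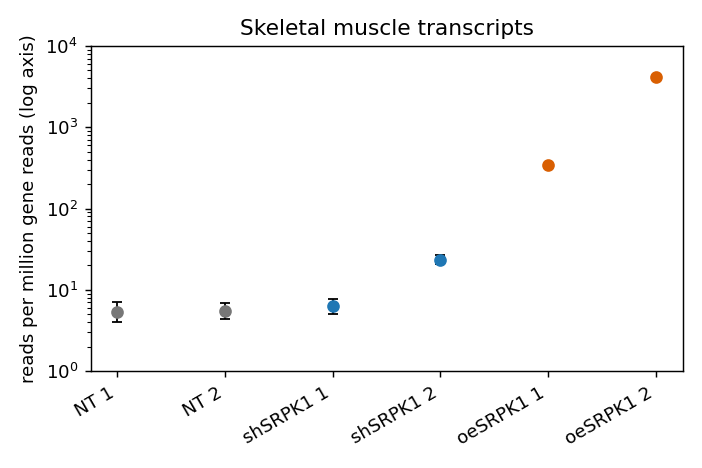
Summed counts of 52 muscle markers as CPM of all gene reads (log axis) in each library, with 95% intervals for counting error. The values are 347 in oeSRPK1 1 and 4205 in oeSRPK1 2, against 5.36 and 5.57 in NT.

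Between oeSRPK1 and shSRPK1, transfected with different vectors, most tested genes on the MAPK list were called higher in oeSRPK1. So were 19 of the 37 tested on the NF-kB and inflammatory list, while most NRF2 targets and mitochondrially encoded genes were called lower. Of the MAPK pathway output list, 20 of 28 genes were higher and 1 was lower (20 and 1 adjusted over the list alone, median 1.0). SPRY2, a feedback inhibitor of the pathway (2.10 ± 0.14), MAFF (2.46 ± 0.17), HBEGF (2.61 ± 0.20) and EPHA2 (1.82 ± 0.16) had edgeR adjusted p = 0.00056, 0.000584, 0.000684 and 0.00137. Of NF-kB and inflammatory genes, 19 of 37 were higher and 1 was lower (23 and 1 adjusted over the list alone), with TRAF1 (3.0 ± 0.17), BIRC3 (2.67 ± 0.18) and the cytokines IL1B (3.94 ± 0.28) and IL1A (3.76 ± 0.27) at edgeR adjusted p = 0.000311, 0.000584, 0.00061 and 0.00061. Of NRF2 targets, 22 of 31 were lower and 0 higher (25 and 0 adjusted over the list alone), with TKT (-1.47 ± 0.14), ABCC3 (-1.74 ± 0.20) and EPHX1 (-1.79 ± 0.22) at edgeR adjusted p = 0.00153, 0.00256 and 0.00302. Camera gave these 3 lists adjusted p = 4.49e-19, 9.16e-17 and 4.72e-18, and adjusted p = 0.389, 0.437 and 0.495 with an estimated correlation. The NRF2 median relative to NT was -0.54 in shSRPK1 1 and 0.08 in shSRPK1 2. Without oeSRPK1 1, 5 genes of MAPK pathway output and 6 of NF-kB and inflammatory genes were called higher and 2 NRF2 targets lower. Without shSRPK1 2, 31 of NF-kB and inflammatory genes were called higher, and without oeSRPK1 2, 12 were.

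Of 46 extracellular matrix genes, 20 were lower and 2 higher in oeSRPK1 than in shSRPK1 (23 and 5 adjusted over the list alone), with COL8A1 (-1.80 ± 0.15), NID2 (-2.28 ± 0.22), COL5A2 (-1.11 ± 0.12) and EFEMP1 (-1.81 ± 0.23) at edgeR adjusted p = 0.00108, 0.00153, 0.00229 and 0.00314. Of 37 genes of cholesterol biosynthesis and SREBP targets, 16 were lower and 0 higher (19 and 1 adjusted over the list alone), with SREBF2 (-1.10 ± 0.14), MVD (-1.50 ± 0.20), SCD (-1.56 ± 0.24) and HMGCS1 (-1.14 ± 0.22) at edgeR adjusted p = 0.00313, 0.00333, 0.00667 and 0.0141. Of 15 mitochondrially encoded genes, 11 were lower and 0 higher (11 and 0 adjusted over the list alone), with MT-ND4L (-1.33 ± 0.15) and MT-ND4 (-1.10 ± 0.15) at edgeR adjusted p = 0.00228 and 0.00353. Camera gave these 3 lists adjusted p = 1.04e-06, 1.40e-05 and 1.36e-08, and adjusted p = 0.389, 0.747 and 0.433 with an estimated correlation. With NT 1, NT 2, shSRPK1 1, shSRPK1 2, oeSRPK1 1 and oeSRPK1 2 left out in turn, 15, 14, 27, 27, 1 and 12 extracellular matrix genes, 6, 6, 18, 26, 0 and 4 of cholesterol biosynthesis and SREBP targets, and 8, 8, 13, 13, 0 and 6 mitochondrially encoded genes were called lower.

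Some genes of the SR proteins list were called lower in oeSRPK1 than in shSRPK1, and the list passed camera (adjusted p = 0.00364), but not with an estimated correlation (adjusted p = 0.495 with an estimated correlation). Its medians relative to NT were 0.25 and 0.16 in shSRPK1 and -0.039 and -0.060 in oeSRPK1. Against NT it did not pass in oeSRPK1 (camera adjusted p = 0.413), where 5 genes fell and 0 rose (3 and 0 adjusted over the list alone), and 1, 0, 10, 10, 0 and 0 were called lower with the libraries left out in the order above. Between oeSRPK1 and shSRPK1, 14 of its 37 genes were lower and 3 higher (14 and 5 adjusted over the list alone, median -0.17), with LUC7L3 (-1.36 ± 0.13), LUC7L (-1.27 ± 0.14), SRRM1 (-0.99 ± 0.13) and ARGLU1 (-0.91 ± 0.12) at edgeR adjusted p = 0.00153, 0.00199, 0.00333 and 0.00373. The 3 that were higher, named after their values were seen, were SRSF6 (0.60), SRSF8 (0.62) and SCAF8 (0.61). With the libraries left out in the order NT 1, NT 2, shSRPK1 1, shSRPK1 2, oeSRPK1 1 and oeSRPK1 2, 9, 9, 16, 17, 1 and 5 genes of the SR proteins list were called lower. Of the 68 interferon-stimulated genes, 13 were higher in oeSRPK1 than in shSRPK1 and 3 lower (13 and 3 adjusted over the list alone, median 0.35), with ISG20 (1.44 ± 0.18), HLA-F (0.88 ± 0.13) and ISG15 (1.20 ± 0.21) at edgeR adjusted p = 0.00302, 0.00472 and 0.00811. Camera gave adjusted p = 0.00479, and adjusted p = 0.878 with an estimated correlation. In the same order, 8, 8, 13, 38, 0 and 2 interferon-stimulated genes were called higher, and without shSRPK1 1, 13 were called lower and the list did not pass camera (adjusted p = 0.856).

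Among single genes, KRT7 (chromosome 12, 52232520 to 52252186, plus strand) stood 3.81 ± 0.20 higher in oeSRPK1 than in shSRPK1 (edgeR adjusted p = 0.000311). STK32A had 0 and 4 reads in shSRPK1 against 163 and 25 in oeSRPK1, and PAPPA2 had 2 and 1 against 77 and 13 (edgeR adjusted p = 0.00297 and 0.00163). PI15 (-4.94 ± 0.97), the reductase AKR1B10 (-3.34 ± 0.67), ADGRG2 (-3.32 ± 0.78), ALDH3A1 (-3.10 ± 0.45), CBLN2 (-2.94 ± 0.69) and the transporter SLC47A2 (-2.91 ± 0.31) were lower, with edgeR adjusted p = 0.0296, 0.0272, 0.0385, 0.00845, 0.0304 and 0.00184. The shSRPK1 libraries differed in PI15 (502 reads in shSRPK1 1 and 1795 in shSRPK1 2), AKR1B10 (4129 and 8904), ADGRG2 (160 and 510) and CBLN2 (91 and 247). NT had 339 and 537, 4789 and 6637, 127 and 171, and 41 and 57 reads of them. The sizes of those differences thus rest in part on shSRPK1 2. HSPA6 (-3.52 ± 0.36) and RPLP0P2 (3.94 ± 0.37), with edgeR adjusted p = 0.00178 and 0.0015, have near-identical relatives and are uncertain. In all, 3361 genes differed, 1690 higher and 1671 lower, while 5597 had an unadjusted p under 0.05. The count was 1576 without NT 1, 1500 without NT 2, 5476 without shSRPK1 1, 6152 without shSRPK1 2, 144 without oeSRPK1 1, 955 without oeSRPK1 2, and 1505 when only the libraries of both groups were fitted.

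**Figure D3:**
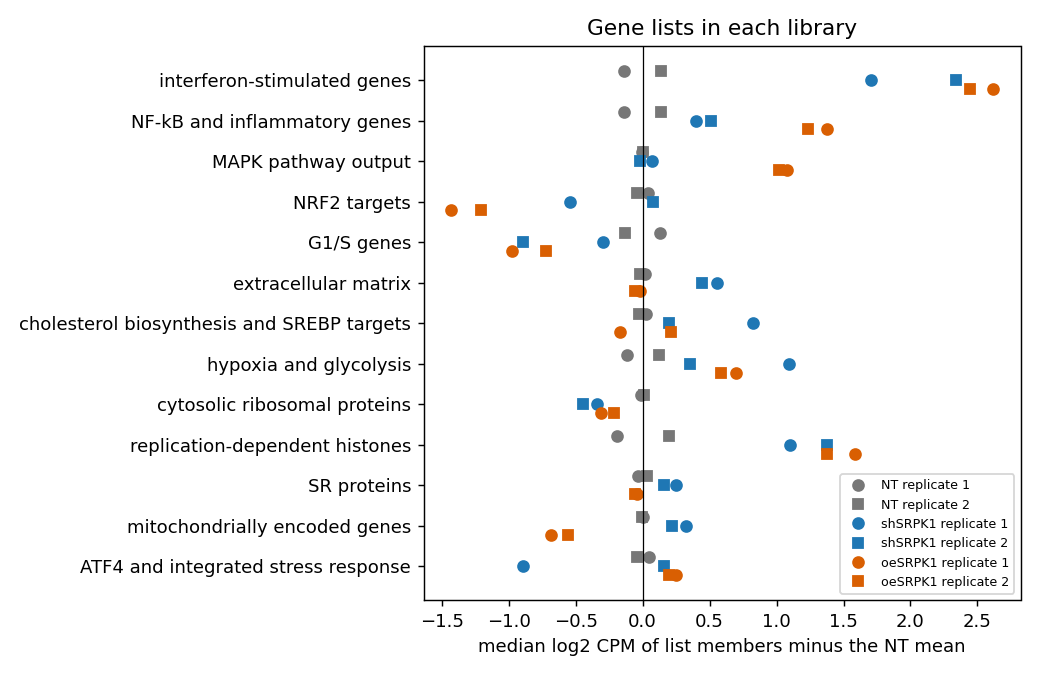
Median log2 CPM of the members of 13 gene lists in each library, minus the mean of the NT libraries; circles are replicate 1 and squares replicate 2 of each group. Interferon-stimulated genes lie between 1.71 and 2.62 in all transfected libraries, while the MAPK list lies near 0 in shSRPK1 and at 1.08 and 1.02 in oeSRPK1.

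Set side by side, the comparisons of both transfected groups with NT shared 599 called genes, of which 541 changed in the same direction and 58 in opposite directions. The 337 genes higher in both compare with 89.3 for independent lists of those sizes, and the 204 lower in both with 52.2. The 30 genes higher in shSRPK1 and lower in oeSRPK1 compare with 75.6, and the 28 of the reverse kind with 61.6. All 54 interferon-stimulated genes called in both rose in both. Across 14732 genes, which are not independent replicates, the fold changes correlated with Pearson's r of 0.448 and Spearman's rho of 0.337, and 61.2% had the same sign. In 20 simulations of unchanged groups that shared simulated NT libraries, r had a median of 0.486, rho of 0.455 and the same-sign share of 66.3%. The simulations held no real changes and had the same spread in all groups. The observed r, rho and share therefore do not tell a shared response from shared controls. The covariance was 0.243 in the data and 0.0629 in the simulations. The value in the data includes muscle transcripts with few or no reads in NT, whose fitted fold changes are no measure of size. How much of the covariance they make up was not tested, so it does not decide the question either. In those simulations 0 to 3 genes were called in both in the same direction and 0 in opposite directions. With only 2 NT libraries the controls were not split, and part of the excess may come from the shared controls. Without NT 1, NT 2, shSRPK1 1, shSRPK1 2, oeSRPK1 1 and oeSRPK1 2, the genes called in the same direction were 26, 40, 1817, 2007, 78 and 128, and those in opposite directions 1, 1, 485, 581, 2 and 5.

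Of the 58 genes called in opposite directions against NT, KRT7, the chemokine CX3CL1 (-1.33 in shSRPK1 and 1.37 in oeSRPK1), NEBL (-1.70 and 1.29), CADPS, a factor of vesicle release (-1.18 and 1.36), CD22 (-1.31 and 1.12) and the protease PLAU (-1.04 and 1.73) fell in shSRPK1 and rose in oeSRPK1. The basement membrane protein NID2 (1.11 and -1.17) and SLC16A4-AS1 (1.56 and -1.31) did the reverse, the second uncertain as an antisense gene counted without a stated strand. Between oeSRPK1 and shSRPK1, where a difference follows from the choice of such genes, CX3CL1 differed by 2.70 ± 0.27, NEBL by 2.99 ± 0.33, CADPS by 2.55 ± 0.28, CD22 by 2.43 ± 0.25 and PLAU by 2.77 ± 0.27, with edgeR adjusted p = 0.00245, 0.00225, 0.00218, 0.00176 and 0.00176.

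**Figure D4:**
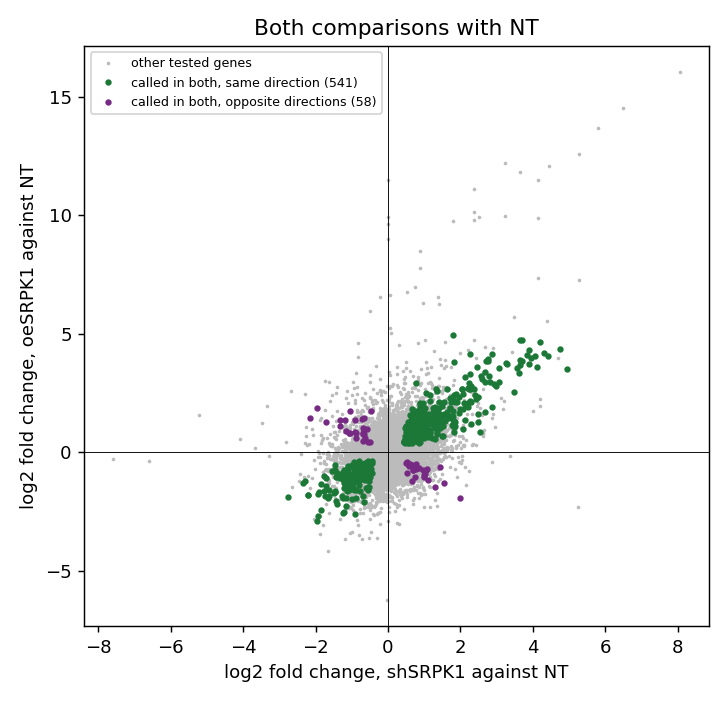
Log2 fold change of each tested gene in oeSRPK1 against NT (vertical) and in shSRPK1 against NT (horizontal). The 541 genes called in both in the same direction are green and the 58 called in opposite directions purple; fitted values of genes with near 0 reads in NT, the muscle transcripts among them, reach the top of the plot and are no measure of size.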

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

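The tests of the muscle markers not looked at before, of olfactory receptors and of nuclear RNAs were chosen before their results were seen, and all other tests in this part, as well as the use of 3 abundant muscle transcripts, were chosen after. No library stood in a group large enough for a test of single samples. Reads in no annotated gene stood above both NT libraries in shSRPK1, at 9.81% and 11.1% of the total in shSRPK1 1 and shSRPK1 2 (NT 8.22% and 9.31%), but not in oeSRPK1 (8.60% and 8.13%). Reads aligned to several places stood above both NT libraries in both transfected groups, at 13.1% and 12.5% in shSRPK1 and 12.9% and 12.8% in oeSRPK1 (NT 11.95% and 12.3%). With 2 libraries against 2, such separations can arise by chance.

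Muscle transcripts such as MYH7 (0 reads in both NT libraries, 0 and 61 in shSRPK1, 2399 and 4905 in oeSRPK1) and TTN (2 and 2, 1 and 13, 558 and 1131) were the first pattern. Against induction by SRPK1, the CPM of the markers was a median of 12.2 times higher in oeSRPK1 2 than in oeSRPK1 1 (quartiles 9.86 and 13.9), while SRPK1 itself had 190.3 normalised CPM in oeSRPK1 1 and 168.0 in oeSRPK1 2. Abundant muscle transcripts were missing, with 0 reads of MYL2, 0 of COX6A2 and 1 of PGAM2 over both oeSRPK1 libraries. Their absence speaks against whole muscle RNA, but they were picked after their counts were seen and do not decide it. In the test fixed beforehand, the median count ratio was 1.47 over 14 further markers (quartiles 0.979 and 2.09). Over the first 22 it was 2.22 (quartiles 2.05 and 2.43), so the bound of 1.5 times was passed narrowly and within the spread. Among the 14, SMPX, PYGM, MYPN, CMYA5 and MYOM2 had reads in every library, and the lowest ratios (0.125, 0.949, 0.254, 1.07 and 0.308). These pull the median down, so the test cannot decide the question either. Reads of muscle of another organism or from another library cannot be told apart from the rest, since 7 of 32 further markers had no reads in either oeSRPK1 library and read sequences were not analysed here; of the markers, NT expressed 2 at 1 CPM or more. With 39 tested genes left out, 3114 genes were called in oeSRPK1 against NT. The genes left out were the tested markers and those with normalised CPM over 10 times higher in oeSRPK1 2 than in oeSRPK1 1. Any muscle reads in other genes stayed in, so this count does not show whether they affected other calls.

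The changes shared by both transfected groups were the second pattern. Of the 599 genes called in both, 9.68% changed in opposite directions (2.44% to 22.4% with 1 library left out), but an opposite response to less and more SRPK1 cannot be told apart from other effects by this share, since SRPK1 passed against NT in neither group and both transfection and shared NT libraries may favour calls in the same direction. Chance values of simulated shared NT libraries gave at most 3 genes called in both in the same direction in 20 simulations, against 541 in the data. Those simulations had the same spread in all groups, unlike the data. Transfection with plasmid DNA and a lipid reagent may account for part of the pattern, the 54 shared interferon-stimulated genes included, but 0 libraries of a transfected control were at hand, so transfection cannot be told apart from an effect of both constructs. Whether SRPK1 itself changes these genes was not tested.

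Reads outside annotated genes in shSRPK1 were the third pattern. Genomic DNA would raise olfactory receptor genes, which are silent in most cells, and their summed CPM in the lower shSRPK1 library was 1.09 times that of the higher NT library, on 10 to 25 reads in each of these 4 libraries, too few to decide. Nuclear RNA was probed with 7 nuclear-retained RNAs, whose median log2 fold change was 0.18 in shSRPK1 (quartiles -0.16 and 0.50) and 0.18 in oeSRPK1, between the bounds set for and against it. Neither source can be told apart from an effect of the hairpin or from chance differences between libraries, and either may raise the share. No biological explanation was tested for this pattern.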

How the results depend on the processing

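Thinning, offsets on GC content and length, the omission of muscle transcripts and limma-voom with a spread per group were chosen after the data were seen. The counts of called genes depended most on which libraries entered; the cause was not tested. With 1 library left out in turn, the genes changed, higher and lower ranged from 29 to 4595, 24 to 2355 and 5 to 2240 in shSRPK1 against NT, from 293 to 6415, 216 to 3058 and 69 to 3363 in oeSRPK1 against NT, and from 144 to 6152, 106 to 2843 and 38 to 3309 in oeSRPK1 against shSRPK1. Genes called in both comparisons with NT ranged from 26 to 2007 in the same direction and from 1 to 581 in opposite directions, and the correlation of fold changes from 0.307 to 0.553. The SRPK1 log2 fold change ranged from -0.37 to -0.062, from 0.17 to 0.38 and from 0.33 to 0.63, keeping its sign. The fewest calls came without NT 1 or oeSRPK1 1, and the most without a shSRPK1 library, where the spread within shSRPK1 no longer enters. Each of these fits left a group of 1 library. With only the libraries compared, 129 genes changed in shSRPK1 against NT (89 higher, 40 lower), 6331 in oeSRPK1 against NT (3090 and 3241) and 1505 in oeSRPK1 against shSRPK1 (759 and 746), 99 were shared in the same direction and 4 in opposite directions, and SRPK1 stood at 0.27 in oeSRPK1 against NT (edgeR adjusted p = 0.0232) and 0.50 in oeSRPK1 against shSRPK1 (0.0920). With a spread per group, limma-voom called 6287 genes in oeSRPK1 against NT (3260 and 3027) and 90 in opposite directions, with SRPK1 at 0.29 (adjusted p = 0.0286). An adjusted p under 0.01 left 181 genes (122 higher, 59 lower), 988 (585 and 403) and 970 (481 and 489) in the 3 comparisons, and a minimum of 2-fold left 470 (317 and 153), 1232 (729 and 503) and 1258 (600 and 658), as stricter thresholds do. With no filter 2616 genes changed in shSRPK1 against NT (1541 and 1075), 2179 were lower in oeSRPK1 against NT and 2615 lower in oeSRPK1 against shSRPK1, with 1034 shared in the same direction and 174 in opposite directions; the cause was not tested. Thinned to the shallowest library, 364 genes were lower in shSRPK1 against NT and 38 were called in opposite directions, on fewer reads. With offsets on GC content and length, SRPK1 stood at 0.42 in oeSRPK1 against shSRPK1 (edgeR adjusted p = 0.0529; the cause was not tested). The numbers of the replicates did not pair the libraries, since deviations of same-numbered libraries correlated at 0.010, -0.019 and 0.023; with a replicate block 1006, 2639 and 2846 genes changed and SRPK1 stood at 0.50 in oeSRPK1 against shSRPK1 (edgeR adjusted p = 0.0609; the cause was not tested). Of the 53 list calls, 48 to 53 were kept under each alternative run on the lists but 3: fry kept 20, an estimated correlation 0, and the fit without shSRPK1 1 kept 42. Among the list calls, camera turned direction without shSRPK1 1 for 2 lists in shSRPK1 against NT. These were the ATF4 list (median 0.17, lowest -0.87 without shSRPK1 2) and G2/M genes (-0.021, highest 0.40 without shSRPK1 2). It also turned for G1/S genes in oeSRPK1 against shSRPK1 (0.039, lowest -0.64 without shSRPK1 2). The G2/M list in oeSRPK1 against shSRPK1, no call in the main fit, turned direction without shSRPK1 2. Its median was -0.23 there and highest, 0.21, without shSRPK1 1. The cause was not tested. No scaling moved the median of all genes by over 0.1. Depth limits oeSRPK1 2 most, where 3 counts stood for 0.776 CPM.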

Other observations

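The genes in this part come from the lists and the rule fixed before the data were examined, and no test in it was chosen after. The endothelial growth factor VEGFC rose in both comparisons with NT, by 1.58 ± 0.12 (log2 fold change ± SE, n = 2 per group) in shSRPK1 and by 1.32 ± 0.12 in oeSRPK1 (edgeR adjusted p = 0.00134 and 0.000824). Of 38 angiogenesis factors, 14 rose and 6 fell in oeSRPK1 (14 and 12 adjusted over the list alone), and 6 rose and 2 fell in shSRPK1 (7 and 3 adjusted over the list alone). Camera gave that list adjusted p = 0.0125 and 0.0288, and adjusted p = 0.433 and 0.448 with an estimated correlation. With NT 1, NT 2, shSRPK1 1, shSRPK1 2, oeSRPK1 1 and oeSRPK1 2 left out in turn, 4, 5, 20, 20, 4 and 11 angiogenesis factors were called higher in oeSRPK1 and 1, 1, 14, 14, 1 and 1 in shSRPK1, where camera did not pass without shSRPK1 1 (adjusted p = 0.0722). Of the p53 targets, ZMAT3 fell in both groups (-1.44 ± 0.18 in shSRPK1 and -1.07 ± 0.18 in oeSRPK1, edgeR adjusted p = 0.00722 and 0.0074), while CDKN1A, an inhibitor of the cell cycle, rose in oeSRPK1 (0.96 ± 0.13, edgeR adjusted p = 0.00348). The list of 34 p53 targets passed camera in none of the 3 comparisons (adjusted p = 0.221, 0.712 and 0.146), but passed without shSRPK1 2 in shSRPK1 against NT (adjusted p = 0.000422) and in oeSRPK1 against shSRPK1 (adjusted p = 1.23e-05). The receptors EGFR (1.80 ± 0.16) and MET (1.56 ± 0.21), the matrix protein TNC (2.17 ± 0.19) and the transcription factor SOX9 (1.51 ± 0.12) rose in oeSRPK1, with edgeR adjusted p = 0.000596, 0.00312, 0.000682 and 0.000454, while CHI3L1 fell (-2.33 ± 0.27, 0.00171). CHI3L1 is an exception in the list of the glioblastoma mesenchymal state, where 9 of 28 genes rose and 2 fell in oeSRPK1 (15 and 3 adjusted over the list alone, median 0.54; camera adjusted p = 9.21e-05, and adjusted p = 0.433 with an estimated correlation), and 3, 4, 21, 21, 3 and 6 were called higher with the libraries left out in the order above. EGR1, an immediate early gene, fell in oeSRPK1 (-2.19 ± 0.17, edgeR adjusted p = 0.000441), although 9 of 30 genes of its list rose there and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.00106, and adjusted p = 0.448 with an estimated correlation). In the order above, 2, 5, 18, 18, 2 and 4 immediate early genes were called higher in oeSRPK1. In the heat shock list, 4 of 29 genes rose and 0 fell in shSRPK1 (4 and 1 adjusted over the list alone), among them DNAJB4 (1.01 ± 0.19), CHORDC1 (0.78 ± 0.15) and SERPINH1 (0.63 ± 0.12) with edgeR adjusted p = 0.0222, 0.0208 and 0.0231. The list as a whole did not pass camera there (adjusted p = 0.255), with medians relative to NT of 0.10 in shSRPK1 1 and -0.065 in shSRPK1 2, but passed without shSRPK1 2 (adjusted p = 0.00163). Its median was -0.12, its mean 0.49 and its camera direction down in oeSRPK1 against NT (adjusted p = 0.815).

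The libraries of shSRPK1 stood apart from each other in several lists. Relative to NT, the median of the ATF4 and integrated stress response list was -0.89 in shSRPK1 1 and 0.16 in shSRPK1 2, against 0.25 and 0.20 in oeSRPK1. That of the list of metallothioneins, which also holds the zinc exporter SLC30A1 and the transcription factor MTF1, was 1.84 and -0.06, against 2.05 and 2.00 in oeSRPK1, where 4 of its 7 genes rose and 0 fell (6 and 0 adjusted over the list alone), SLC30A1 by 1.58 ± 0.15 (edgeR adjusted p = 0.000962). Camera gave the list adjusted p = 0.000101 in oeSRPK1, and adjusted p = 0.495 with an estimated correlation. With the libraries left out in the order above, 1, 1, 6, 7, 1 and 2 genes of that list were called higher in oeSRPK1. The G2/M median was 0.39 in shSRPK1 1 and -0.02 in shSRPK1 2.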
